A study of Mus musculus with 12 samples.

How the data were processed

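H3K27ac ChIP-seq had been run on 6 individual mouse hearts at postnatal day 0, 3 WT and 3 edKO, with 6 matched input samples, per the labels. Hearts were fixed with 2 crosslinkers (DSG and formaldehyde) and their chromatin sheared by sonication, per the labels. The input samples have no list of their own and were not used here. The tools named in the submitters' processing notes are cutadapt, BWA, SAMtools and MACS2, without versions, and the builds mm10 and GRCm38. Whether inputs served as MACS2 controls, and the MACS2 settings, are not given in the sources used here.

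The authors deposited 1 list of called peaks per heart in the narrowPeak format, so peaks were called on each heart and not on pooled hearts. Each deposited entry gives a start, an end and a summit position, which are coordinates in mm10. The deposited signal column is the fold enrichment of the peak, a ratio to background. The deposited significance columns are the −log10 p-value and −log10 q-value of each peak. The smallest −log10 q in each list lies just above that of a q-value of 0.05. The fold and −log10 values are the authors' own and were used only to rank or filter peaks within a list. A region with several summits fills several entries: the lists held 102178, 110348 and 111137 entries in WT 1, 3 and 4, and 80673, 80182 and 114098 in edKO 1, 3 and 6. Entries of the same region were merged into distinct regions. Per-heart read depth is unknown, and the labels give only an average over the series. A longer list can come from deeper sequencing as well as from more marked chromatin, so no counting interval is given, and a region missing from a list is one that was not called, not one without the mark.

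Gene positions came from a RefSeq gene table of GRCm38.p6, the same build as mm10, with 21887 protein-coding genes. The table gives the start and end of each gene without strand or exons, and no genome sequence was used. Some planned steps were changed for this reason. Promoters were replaced by both ends of each gene (1 kb on each side), the nearest transcription start by the nearest gene body (within 100 kb), and the window around the transcription start by 5 kb around both gene ends. The planned search for 12 motifs in genotype-restricted regions was not run. Of 503 genes in the fixed lists, 502 were matched by symbol.

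For each gene, the base pairs covered by peaks within the gene body and 10 kb on each side were summed per heart. The values were taken as log2(bp + 200) and centred per heart on the mean over genes covered in all 6 hearts. Loci with a mean under 500 bp were left out. Differences between genotypes were tested with limma 3.58.1 in R 4.3.3 (trend, robust empirical Bayes) with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change at loci with little covered length. The 20 gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. They cover fatty acid oxidation, fatty acid uptake and lipid storage, glycolysis, the tricarboxylic acid cycle, the respiratory chain, RXR and its partners, retinoid and LXR responses, metabolic regulators, cardiac genes, the cell cycle, markers of 7 other cell types and control genes.

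Regions of the 6 lists were merged into a union at 1 bp overlap, and each was scored as called or not in each heart. Counts of regions called in all hearts of a genotype and in none of the other were set beside the other choices of 3 hearts. A single region in 3 against 3 hearts cannot go below an exact p of 0.1, so no region was tested alone. List totals were compared by exact permutation tests over 20 assignments, and gene lists near restricted regions by Fisher's exact test against regions called in 3 hearts of mixed genotype. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

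The genes named in the text follow a rule set before the data were examined. It takes the RXR genes, the 12 largest falls and 8 largest rises past the threshold with the genotypes separated (places left over going to separated loci with the smallest unadjusted p), and the 3 members with the smallest unadjusted p of each called list. It also takes the 5 best-ranked restricted regions per genotype and the genes at the 5 widest joined clusters of the WT hearts. Other list members are named to show the range of a list or because they passed adjusted over the list alone, and were chosen after their values were seen. Some items that the rule or a list would name are not reported here. The test was tried on simulated data for this comparison, with known changes placed at some of 14220 loci. It recovered 69.1% of 97 loci changed by a log2 of -1 and 92.7% of 96 loci changed by -2, with 10 false calls. Many more loci were changed there than were called in the real hearts. That eases the adjusted threshold, so these shares need not hold for the real comparison.

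Alternatives set before the data were examined were stricter lists (−log10 q of at least 5), equal list length (the best 47971 regions of each list), other overlap and joining rules, no centring, quantile normalization, pseudocounts of 50 and 1000 bp, no filter, the gene body alone, autosomes alone, wider gene ends, a replicate block, an estimated correlation, and leaving out each heart. Alternatives chosen after seeing the data were the window at both gene ends, counting each region for its nearest gene alone, summit entries in place of regions, equal list length for the lists near restricted regions, and a covariate for a marked Xist gene. For the gene lists, stricter lists, quantile normalization, both pseudocounts, no filter, the gene body alone and autosomes alone were also chosen after seeing the data, having been set beforehand for gene loci only.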

Results

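H3K27ac, a histone mark of active promoters and enhancers, was mapped by ChIP-seq in whole mouse hearts at postnatal day 0. Wild-type hearts (WT, n = 3, numbered 1, 3 and 4) were compared with hearts lacking Rxra and Rxrb in cardiomyocytes (edKO, n = 3, numbered 1, 3 and 6). Rxra and Rxrb encode retinoid X receptors, nuclear receptors that bind DNA as partners of PPARs, LXRs, retinoic acid receptors and other receptors. The series concerns the metabolic maturation of the newborn heart, and the comparison asks where the mark depends on RXR in cardiomyocytes. Each heart is a biological replicate, per the labels, and has its own list of called peaks. The WT lists held 57976, 62882 and 66325 distinct regions, and the edKO lists 47971, 48274 and 67706. Sequencing depth per heart is unknown, so the length of called peaks at a gene was compared, and peak scores were not compared between hearts.

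The loci of the targeted genes, each the gene body plus 10 kb on each side, stayed marked in both genotypes. The Rxra locus (gene body at chromosome 2, 27676445 to 27763319, mm10) had 11157, 15540 and 18868 bp of called peaks in the WT hearts, against 15107, 8682 and 18432 bp in the edKO hearts. The Rxrb locus (gene body at chromosome 17, 34031812 to 34038403) had 5138, 5143 and 5323 bp in WT, against 5250, 4246 and 5226 bp in edKO. Rxrb was not among the loci tested with each region counted for its nearest gene alone, so this length is not that of Rxrb alone. Neither passed the test, with log2 differences of -0.06 (SE 0.26, limma adjusted p = 0.968) for Rxra and 0.00 (SE 0.10, limma adjusted p = 0.999) for Rxrb. Rxrg, the third RXR gene, had 265, 430 and 0 bp in WT and 0, 0 and 623 bp in edKO, too little to be tested. A histone mark in whole hearts, in which other cell types keep both genes, does not check the deletion.

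Of the 15 gene loci past the threshold, all with less H3K27ac-marked length in edKO hearts, 5 are in the fixed lists of fatty acid genes (Acot1, Acot2, Hadha, Acsl1 and Decr1). At Acot1 and Acot2, which encode thioesterases that release free fatty acids from acyl-CoA, called peaks covered 5633 ± 593 and 5909 ± 297 bp in WT hearts, against 942 ± 32.7 and 1688 ± 223 bp in edKO hearts (mean ± SD, n = 3 per genotype). At the neighbouring thioesterase gene Acot4, which is in neither list, peaks covered 2353 ± 158 bp in WT and 0 bp in each edKO heart, so no fold is given. That length was summed over the gene body and 10 kb on each side. Only part of it lay inside Acot4, and part lay inside the adjoining gene Acot3 (84053370 to 84053924 in WT 1). Hadha, the alpha subunit of the mitochondrial trifunctional protein of beta-oxidation, fell from 9144 ± 1048 to 3307 ± 684 bp. Acsl1, which activates long-chain fatty acids to acyl-CoA, fell from 12477 ± 721 to 5545 ± 222 bp, and Decr1, a reductase needed to oxidise polyunsaturated fatty acids, from 3500 ± 402 to 1305 ± 177 bp.

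On the log2 scale of covered length plus 200 bp, the difference was -2.26 for Acot1 (SE 0.15, limma adjusted p = 0.0063) and -1.61 for Acot2 (SE 0.13, limma adjusted p = 0.0168). It was -1.34 for Hadha (SE 0.14, limma adjusted p = 0.0309), -1.05 for Acsl1 (SE 0.11, limma adjusted p = 0.0309) and -1.21 for Decr1 (SE 0.14, limma adjusted p = 0.0392). Genes outside fatty acid metabolism fell too. Ces1e, a carboxylesterase gene, fell by 1.98 (SE 0.18), from 4370 ± 601 to 907 ± 275 bp. Tuba8, an alpha-tubulin gene, had 2875 ± 366 bp in WT, while 2 edKO hearts had 0 bp and the third 261 bp. The tetraspanin gene Tspan3 (log2 difference -1.29, SE 0.14), the inositol monophosphatase gene Impa2 (-1.26, SE 0.15) and the immunoglobulin-like receptor gene Oscar (-1.36, SE 0.17) fell as well. So did Art1, an ADP-ribosyltransferase gene of skeletal and cardiac muscle (-1.04, SE 0.13). All 12 of these loci stayed lower in every alternative but lost their call in some: Acot1 in 2 of 19, Acot2 in 3 of 19, Acot4 in 6 of 17, Ces1e and Tuba8 in 6 of 18, Oscar in 9 of 18, Hadha in 10 of 19, Acsl1 and Decr1 in 11 of 19, Tspan3 in 12 of 19, Impa2 in 13 of 19 and Art1 in 14 of 18, the last 7 whichever heart was left out. The smallest differences were -1.02 for Acot1, -0.56 for Acot2 and -0.71 for Tspan3 with the gene body alone, -0.34 for Decr1, -0.64 for Acsl1 and -0.48 for Impa2 at both gene ends (chosen after seeing the data), and -0.53 for Art1 with stricter lists. The 12 loci were picked with all edKO hearts below all WT hearts, so leaving out a heart could hardly turn their sign. The remaining loci past the threshold were Pld1, Dlgap3 and Art5, which lie outside the naming rule and were added after their values were seen. Art5 shares every called region with Art1.

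**Figure D1:**
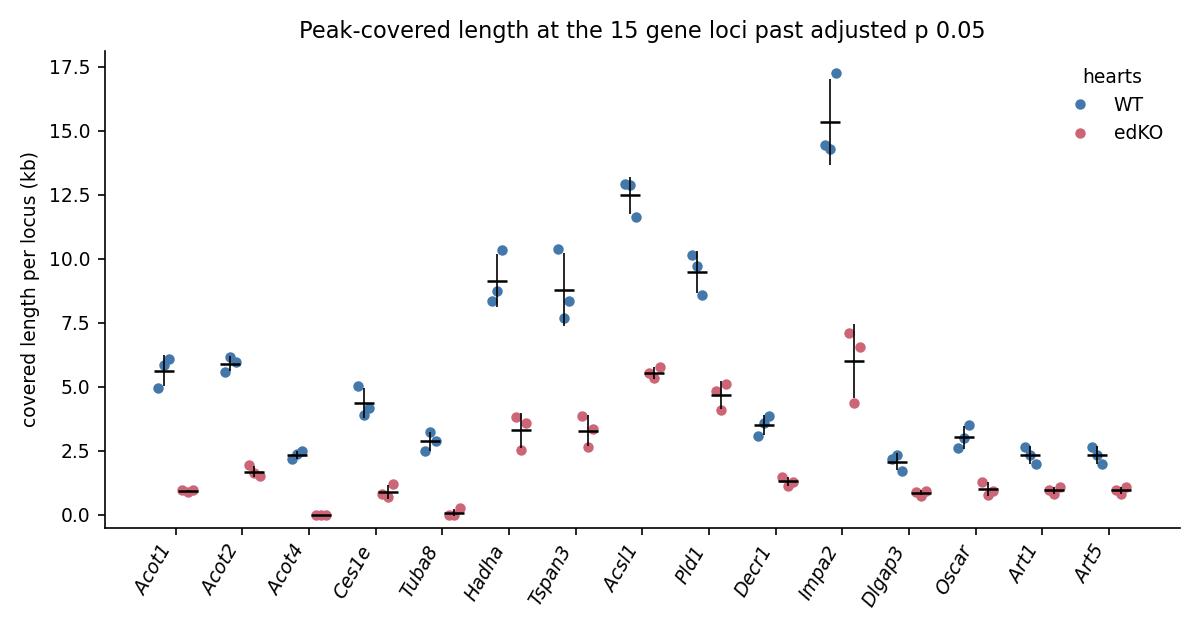
Length covered by called H3K27ac peaks (kb, linear axis) at the gene body plus 10 kb on each side, for the 15 loci past adjusted p 0.05. Each point is 1 heart (WT blue, edKO red), horizontal bars are means and vertical bars 1 SD (n = 3 per genotype). All edKO hearts lie below all WT hearts at each of these loci.

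The thioesterase cluster on chromosome 12 showed the loss region by region. Across the stretch from Acot2 to Acot3, 8, 10 and 13 regions were called in the WT hearts, against 2, 3 and 2 in the edKO hearts. They covered 11684, 13099 and 13207 bp in WT, against 2899, 2524 and 2466 bp in edKO. The peaks left in the edKO hearts lay at 1 end of Acot2 (83987861 to 83993877) and of Acot1 (84009502 to 84017670). Regions at 83998076 to 84000839, 4198 bp from Acot2, and at 84019233 to 84021705, 1562 bp from Acot1, were called in all WT hearts and in no edKO heart. At Hadha (chromosome 5, 30119423 to 30154980) and the adjoining beta subunit gene Hadhb, peaks covered 13715, 14661 and 16574 bp in the WT hearts and 8393, 6595 and 7120 bp in the edKO hearts across the drawn stretch, which takes in an end of Garem2. The region at 30149873 to 30151050, inside Hadha, was called in WT hearts alone.

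**Figure D2:**
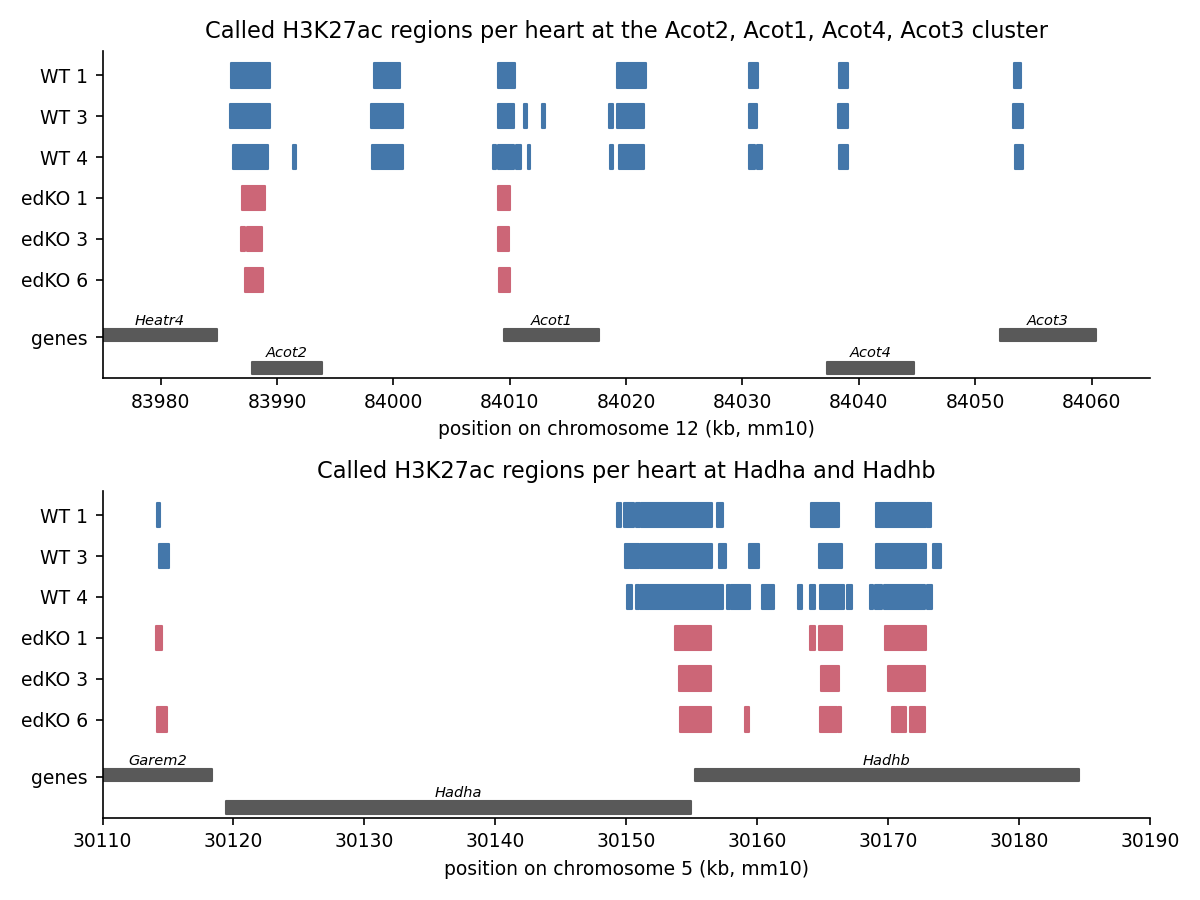
Called H3K27ac regions in each heart (WT blue, edKO red) and gene bodies (grey) at the Acot cluster on chromosome 12 and at Hadha and Hadhb on chromosome 5, with position in kb (mm10) on the horizontal axis. At the Acot cluster the edKO hearts have 2, 3 and 2 regions where the WT hearts have 8, 10 and 13.

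Over 14317 protein-coding gene loci tested with limma, 15 had a lower covered length in edKO hearts at an adjusted p of 0.05 and 0 had a higher one. At an unadjusted p under 0.05, 662 loci were lower and 284 higher. Chance alone would put a share of 0.05 of the 14317 loci there, both directions together. Without centring per heart, 598 were lower and 27 higher. All edKO hearts lay below all WT hearts at 827 loci and above them at 1019, together 12.9% of loci, where chance gives 10%. Of loci with all edKO hearts above all WT hearts, those with the smallest unadjusted p did not pass the threshold. These included the copine gene Cpne7, at 1184 ± 472 bp in WT and 2436 ± 266 bp in edKO (log2 difference 1.06, SE 0.20, limma adjusted p = 0.164). Others were Pde3b, a phosphodiesterase gene (log2 difference 0.62), Peg10, an imprinted gene (0.73), the tropomodulin gene Tmod2 (0.59), the palmitoyltransferase gene Zdhhc21 (0.55), and Cep44 and Fbxo8, which share the same regions (0.44 each). Windows of neighbouring genes overlap: counting each region for its nearest gene alone, an alternative chosen after seeing the data, gave 8 lower loci, 3 of them among the 15, while stricter lists gave 9, equal list length 6 and a covariate for a marked Xist gene, also chosen after seeing the data, 3. The count rested on having all 6 hearts, with 2 lower loci without WT 1, 0 without WT 3, 1 without WT 4, 8 without edKO 1, 4 without edKO 3 and 9 without edKO 6.

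As a group, fatty acid oxidation genes had lower estimates in edKO hearts. Of the 30 genes in the list, 26 had a lower estimate in edKO hearts, and the mean log2 difference was -0.52 (SE over members 0.11). The list was called lower by camera (adjusted p = 2.53e-17 with the preset correlation), a call that was lost with an estimated correlation (adjusted p = 0.263). Hadha, Acsl1 and Decr1 passed over all genes, and 15 genes passed when adjusted over the list alone. These 15 included Hadhb, at 14642 ± 1692 bp in WT and 6962 ± 845 bp in edKO. The windows of Hadhb and Hadha overlap, so some called regions count for both genes and their falls are not independent. The 15 also included Cpt2, which rebuilds acyl-CoA inside mitochondria, at 3120 ± 29.0 and 1250 ± 268 bp. Cpt1b, the muscle form of the entry enzyme, passed too, at 7501 ± 250 and 5126 ± 1060 bp. The medium- and long-chain dehydrogenase genes Acadm (log2 difference -0.12, SE 0.15) and Acadl (-0.05, SE 0.13) did not pass on either basis. The mean level of the list was lower in each edKO heart than in any WT heart, at 0.44 ± 0.14 in WT and -0.08 ± 0.06 in edKO on the centred log2 scale (exact two-sided permutation p = 0.1, the smallest that 3 against 3 hearts allow).

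The list of fatty acid uptake and lipid storage genes followed, with 24 of 32 below 0. Its mean log2 difference was -0.32 (SE over members 0.09) and its median -0.23. The list was called lower by camera (adjusted p = 2.32e-08), and the call was lost with an estimated correlation (adjusted p = 0.263). Only Acot1 and Acot2 passed over all genes. They encode thioesterases, not uptake or storage proteins, and their windows overlap. Adjusted over the list alone, 6 genes passed, Acot1 and Acot2 among them. The others were the uncoupling protein gene Ucp3, at 10520 ± 1661 bp in WT and 5603 ± 453 bp in edKO, the hormone-sensitive lipase gene Lipe, at 10328 ± 303 and 6674 ± 462 bp, Acsl3 and Cidea. Ucp3 missed the threshold over all genes (log2 difference -0.79, SE 0.16, limma adjusted p = 0.21) but passed in 3 of 19 alternatives. These included the gene body alone and each region counted for its nearest gene alone, where the difference was -2.45. Over the 19 alternatives the Ucp3 difference ran from -2.63 to -0.56. The fatty acid transporter gene Cd36 had 30208 ± 4179 bp in WT and 21158 ± 6666 bp in edKO and did not pass. The lipid droplet gene Plin2 (log2 difference -0.05, SE 0.11) and the lipoprotein lipase gene Lpl (-0.13, SE 0.12) did not pass either. All 3 edKO hearts lay below all WT hearts in its mean (exact two-sided permutation p = 0.1).

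Sarcomere and calcium handling genes and retinoid and LXR response genes were called lower by smaller amounts. The 37 sarcomere and calcium handling genes had a mean log2 difference of -0.11 (SE over members 0.04, camera adjusted p = 0.00435, and adjusted p = 0.723 with an estimated correlation). The only member past the threshold, over all genes or adjusted over the list alone, was Art1, an ADP-ribosyltransferase gene that is part of neither the sarcomere nor calcium handling. The sodium-calcium exchanger gene Slc8a1 had 32992 ± 882 bp in WT and 23371 ± 4906 bp in edKO, and the calcium channel gene Cacna1c had 55976 ± 3760 and 39454 ± 11830 bp. The 20 tested retinoid and LXR response genes had a mean of -0.15 (SE over members 0.09, camera adjusted p = 0.0237, and adjusted p = 0.723 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Srebf1 (log2 difference -0.37, SE 0.11), Hoxa3 (-1.11, SE 0.35) and Abcg1 (-0.39, SE 0.13) had the smallest unadjusted p. Hoxa3 passed over all genes in 1 of 19 alternatives (limma adjusted p = 0.0162), the replicate block, which leaves 1 residual degree of freedom. In neither list did all edKO hearts lie below all WT hearts (exact two-sided permutation p = 0.2 and 0.5). Without a single heart the mean log2 difference ran from -0.153 to -0.082 in the first and from -0.355 to -0.065 in the second. Neither list was called without WT 4 or with quantile normalization. The first was also not called without edKO 3 or with the gene body alone (adjusted p up to 0.283 over the alternatives), and the second not without WT 3, without edKO 1, with no centring or with stricter lists (adjusted p up to 0.177).

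Other parts of energy metabolism and the other cell types of the heart were not called with the main settings. The 39 respiratory chain and ATP synthase genes had a mean log2 difference of 0.02 (SE over members 0.02), the 26 tricarboxylic acid cycle and ketone use genes 0.04 (SE 0.03), and the 33 glycolysis and glucose use genes -0.03 (SE 0.03). Fibroblast markers had a mean of 0.17 (SE 0.04, 16 of 19 above 0, camera adjusted p = 0.154) and endothelial markers 0.08 (SE 0.03, 17 of 21 above 0, camera adjusted p = 0.344). Fibroblast markers were called higher in 4 alternatives, at equal list length (camera adjusted p = 0.0419), with no centring (adjusted p = 0.0203), without WT 3 (adjusted p = 0.000269) and without edKO 1 (adjusted p = 0.0103). Their mean was -0.03 without WT 1, the heart with the lowest level, and the hearts of the genotypes overlapped (exact two-sided permutation p = 0.7). Smooth muscle and pericyte markers had a mean of 0.10 and erythroid markers 0.01. Leukocyte markers had a mean of -0.01 but a median of 0.06. Neural and Schwann cell markers had a mean of -0.11 but a median of 0.02. They were called lower only with a replicate block (mean -0.58, camera adjusted p = 0.0355), and their mean ran from -0.41 to 0.08 without a single heart. Epicardial markers had a mean of -0.32 (SE 0.27) over 9 genes that went both ways. That mean was -0.60 with a replicate block and 0.13 with the gene body alone (5 genes). Without a single heart it ran from -0.58 to -0.05. Adjusted over that list alone, Krt18, a keratin gene, was lower (1362 ± 409 bp in WT and 222 ± 385 bp in edKO) and Tbx18, an epicardial transcription factor gene, higher (8534 ± 1180 and 10904 ± 881 bp).

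Single members of other lists stood apart from their groups. Cardiac transcription factors had a mean log2 difference of -0.04 and were called lower only with each region counted for its nearest gene alone (camera adjusted p = 0.0253), with Meis2 at 28333 ± 2206 bp in WT and 17612 ± 2696 bp in edKO (limma adjusted p = 0.0106 over the list alone). Cell cycle genes had a mean of -0.01 and a median of 0.03, with Bub1b, a spindle checkpoint kinase gene, at 2394 ± 159 and 851 ± 116 bp and Cdk1, the mitotic kinase gene, at 5366 ± 247 and 3323 ± 543 bp. Fetal cardiac isoforms and stress genes had a mean of 0.00, with the T-type calcium channel gene Cacna1h at 7839 ± 1040 and 2123 ± 1565 bp. Among metabolic transcription regulators (mean -0.05), Nrip1, a nuclear receptor corepressor gene, had 7310 ± 630 and 5018 ± 864 bp. These 5 genes passed only when adjusted over the list alone. RXR and its partner receptors had a mean of -0.05, with the log2 difference of Ppara at -0.13 (SE 0.18). The 20 widely used control genes had a mean of 0.05 (SE 0.02).

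**Figure D3:**
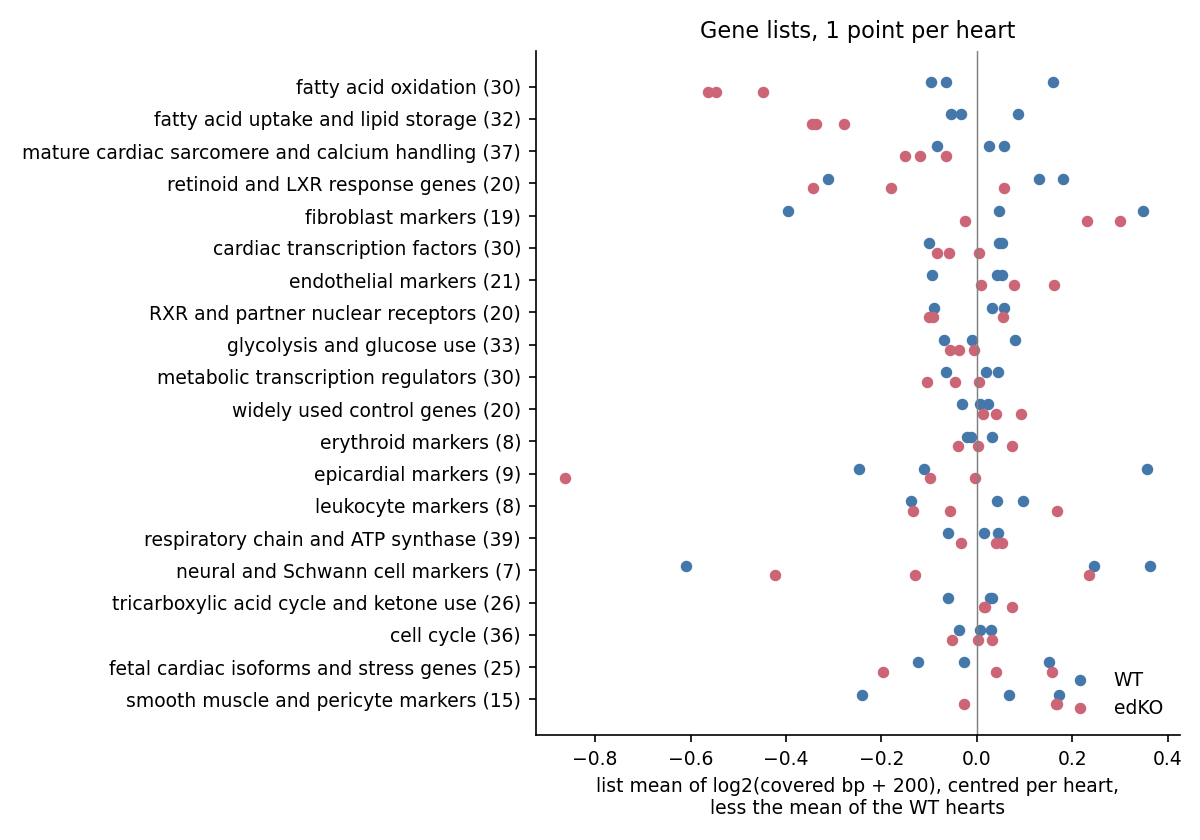
Mean over each gene list of log2(covered bp + 200), centred per heart and shown relative to the mean of the WT hearts, with 1 point per heart (WT blue, edKO red) and the number of genes tested in brackets. For fatty acid oxidation and for fatty acid uptake and lipid storage, all 3 edKO hearts lie below all 3 WT hearts.

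Regions restricted to WT hearts lay near fatty acid genes more often than regions called as often in mixed hearts. Of regions called in all WT hearts and in no edKO heart, 773 had a protein-coding gene within 100 kb, and 8 of these (1.03%) were nearest to a fatty acid oxidation gene. Among regions called in 3 hearts of mixed genotype this held for 4 of 4645 (0.0861%; odds ratio 12.1, two-sided Fisher exact test, adjusted p = 0.000964). Fatty acid uptake and lipid storage genes were nearest to 8 of 773 and 8 of 4645 (odds ratio 6.06, Fisher exact adjusted p = 0.00736), and no other list passed. Regions are not replicates, so these p-values describe the regions of these 6 hearts. Of the 16 WT-restricted regions nearest to these fatty acid genes, 8 lay outside them, 1562 to 39116 bp away, and 8 overlapped a gene body by at least 1 bp. Those that overlapped included regions at Hadha, Mgll, Decr1 (chromosome 4, 15937555 to 15939394), Hadh (chromosome 3, 131250738 to 131252297), Acat1 (chromosome 9, 53601284 to 53602473), Eci2 (chromosome 13, 35026570 to 35027206) and the lipid droplet gene Plin5 (chromosome 17, 56116683 to 56118072). Exons, introns and untranslated regions were not told apart here.

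In all, 853 regions were called in every WT heart and in no edKO heart, and 56 in every edKO heart and in no WT heart. The 18 choices of 3 hearts of mixed genotype gave between 38 and 894 regions, with a median of 248, so neither number lies outside that range. With lists cut to equal length the numbers were 419 and 129, and with stricter lists the first was 513. The strongest WT-restricted regions, by rank within each list, overlapped the gene bodies of Nrip1 (chromosome 16, 76293270 to 76295325), Zranb3 (chromosome 1, 127989237 to 127991300) and Oscar (chromosome 7, 3608170 to 3610027). The Oscar region crossed an end of the gene body (3609813 to 3616157) and lay mostly outside it. A further pair lay 193313 bp from the cardiac transcription factor gene Prox1 (chromosome 1, 190364141 to 190366890) and 161849 bp from Pou3f3 (chromosome 1, 42532028 to 42533918). The strongest edKO-restricted regions overlapped the gene bodies of Pde10a (chromosome 17, 8629585 to 8630413) and Ttc39b (chromosome 4, 83303460 to 83304005), or lay nearest to Nf1, Trim24 and Tlk1 at 14576, 64580 and 62948 bp. The authors' fold enrichment was 12.2 to 18.3 at the Nrip1 region in the WT lists and 5.83 to 7.35 at the Pde10a region in the edKO lists.

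**Figure D4:**
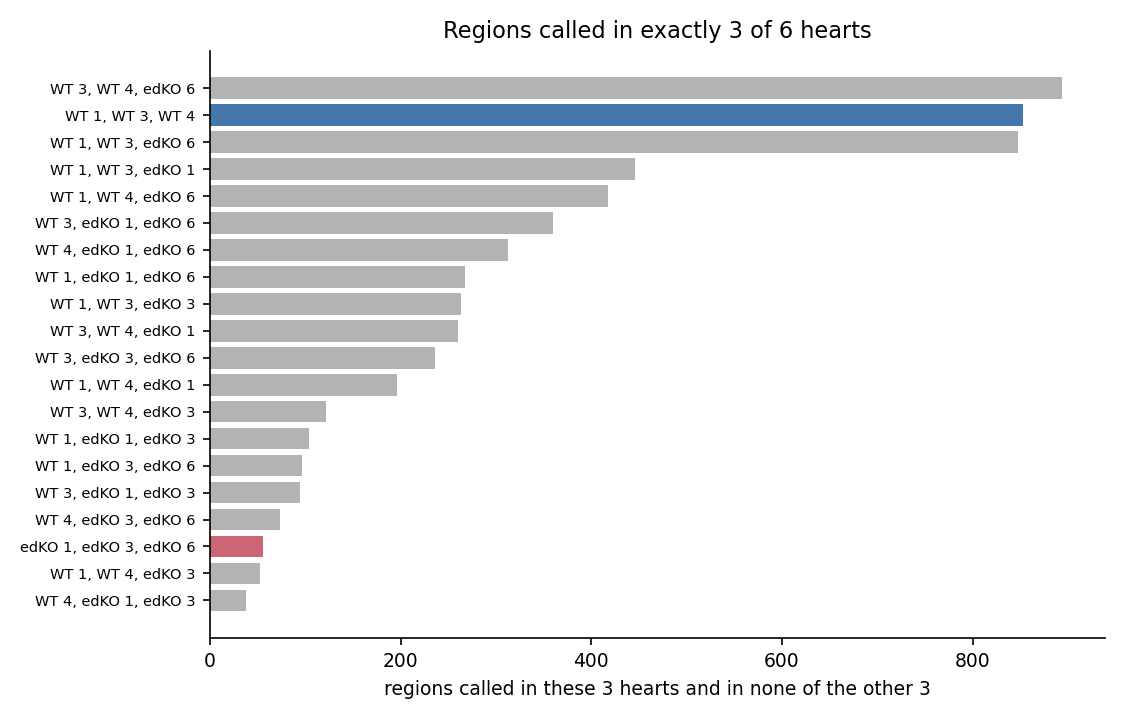
Number of regions called in exactly 3 of 6 hearts, for each of the 20 choices of 3 hearts (all WT blue, all edKO red, mixed grey), on a linear axis from 0. The WT-restricted number, 853, is the second highest, and the edKO-restricted number, 56, is the third lowest.

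At gene ends, where promoters lie at 1 of the ends, most marks were common to both genotypes. A region lay within 1 kb of an end of 11383 genes in all 6 hearts. In all WT hearts and no edKO heart this held for 35 genes. Among them were Eci2, Ucp3, Tuba8, the gluconeogenic genes Pck1 and Fbp2, the organic cation transporter gene Slc22a4 and the keratin gene Krt8. These 7 were picked from the 35 after they were seen. In all edKO hearts and no WT heart it held for 2 genes, Dnaaf4 and Mymk, also named after they were seen. Mixed choices of 3 hearts gave up to 79 genes.

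The widest marked clusters of the WT hearts were marked in the edKO hearts too. With regions within 12 kb joined, the cluster at Tns1 and Rufy4 (chromosome 1, 73902563 to 74125399) had 128 ± 4.74 kb of peaks in WT and 112 ± 19.9 kb in edKO. The cluster at Fignl1, Ddc and Grb10 (chromosome 11, 11808149 to 12039238) had 103 ± 5.42 and 85.3 ± 7.53 kb. The clusters at Dkk3, Mical2 and Micalcl (chromosome 7), at the splicing factor gene Rbm20 (chromosome 19) and at Gtf2e2 and Rbpms (chromosome 8) had 99.7 ± 10.1, 96.4 ± 7.19 and 90.7 ± 3.06 kb in WT, against 89.9 ± 17.6, 85.8 ± 10.8 and 81.3 ± 15.6 kb in edKO. These clusters were chosen by their length in WT hearts, so their lower length in edKO is not a test.

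The lists as a whole did not separate the genotypes. The WT hearts had 62394 ± 4196 regions and the edKO hearts 54650 ± 11308 (exact two-sided permutation p = 0.4), covering 64.9 ± 5.07 and 59.0 ± 9.86 Mb (exact two-sided permutation p = 0.5). Without a single heart, the difference ran from -14272 to -4404 regions and from -9.65 to -0.303 Mb. With summit entries counted in place of regions, chosen after seeing the data, it was -16235 (exact two-sided permutation p = 0.4). Of 79241 regions in the union of the 6 lists, 28396 (35.8%) were called in all 6 hearts and 25475 in a single heart. The mean Jaccard index, the shared share of covered base pairs, was 0.640 over the 6 pairs of hearts of the same genotype and 0.637 over the 9 pairs of different genotype (one-sided p = 0.2 over the 10 splits, by exact enumeration). The sign of this difference turned without WT 1, WT 3 or WT 4, at -0.00338, -0.00281 and -0.00471. The Xist gene, which is marked in females, had 2352 bp of peaks in WT 1, 2080 bp in edKO 6 and 0 bp in the other hearts. No list held a region on chromosome Y, so the sex of the other hearts is not settled by these marks.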

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

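The alternatives with both gene ends, the nearest gene alone, summit entries, the Xist covariate and equal list length near restricted regions were chosen after seeing the data, as were, for gene lists, stricter lists, quantile normalization, both pseudocounts, no filter, the gene body alone and autosomes alone. Of the 15 lower loci, those tested in a setting kept a negative difference in each one (11 were tested with the gene body alone or both gene ends). All edKO hearts lay below all WT hearts at these 15 loci, so leaving out a heart could hardly turn the sign. The number of lower loci was 9 with stricter lists, 6 at equal list length, 8 with each region counted for its nearest gene alone, 3 with the Xist covariate and 0 to 9 without a single heart. Leaving out a heart means fewer samples, and otherwise the cause was not tested. The replicate numbers 1 and 3, the only shared ones, were not shown to pair the hearts (correlation of deviations 0.18, the highest of 9 pairs, and 0.03). With these numbers as a replicate block, which leaves 1 residual degree of freedom, 90 loci were lower, 12 of them among the 15, and 5 lists were called. Higher loci numbered 0 in all settings but leaving out a heart, which gave 0 to 1. Without WT 3, which gave 0 lower loci, 554 of 14245 loci were lower and 243 higher at an unadjusted p under 0.05. Chance alone would put a share of 0.05 of the loci there, both directions together. The fatty acid oxidation list (mean -0.80 to -0.37, highest adjusted p = 2.6e-08) and the uptake and storage list (-0.44 to -0.24, highest adjusted p = 0.000373) were called in all 19 camera alternatives with the preset correlation. With the estimated correlation 0 lists were called, with quantile normalization 2, with stricter lists or the gene body alone 3, and without a single heart 2 to 4. The sarcomere list lost its call in 4 alternatives and the retinoid and LXR list in 6, with adjusted p up to 0.283 and 0.177. Fibroblast markers were called higher in 4 but had a mean of -0.03 without WT 1, and the neural and cardiac transcription factor lists lower in 1 each. For the named genes and these lists, 464 values kept their direction and side of the threshold, 113 lost the threshold, 4 gained it and 12 changed sign, none of them called. Rxra was at 0.120 with stricter lists, 0.119 at equal list length, 0.0169 with quantile normalization, 0.0130 at both gene ends and -0.272 to 0.167 without a heart. Rxrb was at 0.0169 with stricter lists, 0.00203 with a pseudocount of 50 bp, 0.0610 with a replicate block and -0.0486 to 0.0679 without a heart, and Slc8a1 at 0.0168 at both gene ends. WT-restricted regions numbered 513 with stricter lists, 419 at equal list length and 1009 to 2176 without a heart. The edKO-restricted regions numbered 129 at equal list length and 112 to 524 without a heart. Gene ends marked in WT alone numbered 40 to 125 without a heart, and those in edKO alone 2 to 13, or 1 within 2.5 kb. Leaving out a heart eases these criteria. The Jaccard difference, which did not pass its test, was -0.000452 at equal list length and -0.00471 to 0.0160 without a heart. At equal list length the WT-restricted regions were near fatty acid oxidation genes in 6 of 387 cases, against 3 of 3561 mixed regions (odds ratio 18.7, Fisher exact adjusted p = 0.00111), and retinoid and LXR response genes joined the lists that passed (odds ratio 12.4, adjusted p = 0.025). The motif search with its GC-matched alternative and the window around the transcription start were not run. Depth per heart is unknown and limits what a missing region can show.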

Other observations

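The tests of the cardiomyocyte share, of genotype and of xenobiotic and carboxylesterase genes were chosen after the results were seen, and the 3 added gene lists described first were written after the called loci were known. Xenobiotic and carboxylesterase genes, a list written after Ces1e was seen among the lower loci and leaving that gene out, were lower in edKO hearts (14 genes tested, mean log2 difference -0.33, SE 0.16, camera adjusted p = 0.000237 over the 3 added lists, 7.90e-05 unadjusted). With an estimated correlation the unadjusted value was 0.059, no longer past the threshold. The members with the smallest p were Ephx2, an epoxide hydrolase gene, Cyp4b1, Ces1d and Por, and Ces1d shares part of its window with Ces1e. Without Ces1d the mean was -0.23 (SE 0.13, 13 genes), at 0.00099 unadjusted and 0.09 unadjusted with an estimated correlation, so whether detoxification genes fall along with fatty acid genes stays open. Taken as a list, peroxisomal genes gave no such fall (23 genes, mean -0.04, SE 0.05, camera adjusted p = 0.994), with 1 member lower and 1 higher at an unadjusted limma p under 0.05. Genes of mitochondrial translation and import did not either (26 genes, mean 0.03, SE 0.04, camera adjusted p = 0.73, 0.487 unadjusted), so a fall across mitochondrial genes in general is not what these lists show.

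For the lower covered length at fatty acid oxidation loci, shorter edKO lists, and depth as far as it sets list length, are argued against by equal list length, at which the list mean less that of all loci was -0.502 (SE 0.0913); edKO 6, with the longest list (67706 regions), also had a mean of -0.10 against 0.38 in WT 1 (57976 regions). A single heart is argued against by the leave-one-out fits, in which the list mean was at most -0.372, and a general fall of loci of this length by 10000 random lists matched on covered length, the lowest of which had a mean of -0.281 against -0.520. A lower share of cardiomyocytes is argued against by 17 members of the sarcomere and calcium handling list of like covered length. Their mean was -0.113, which left a gap of -0.407 (SE 0.127). These 17 include Art1, which is neither a sarcomere nor a calcium handling gene. Peak height was not matched, and fibroblast markers were called higher in 4 of 19 alternatives, but at -0.03 without WT 1. The lowest WT heart lay 0.353 above the highest edKO heart in the list mean, which restates the pattern and does not test the loss of RXR in cardiomyocytes. That loss and litter stay open, as untested hypotheses, as does any effect of depth beyond list length.

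The shorter lists of edKO 1 and edKO 3 were the second pattern. Regions called in the 4 other hearts but in neither of these numbered 1300, and their median rank within the WT lists reached a percentile of at most 39.0. They were thus weaker than most regions without being the weakest, so shallower lists and a true loss cannot be told apart by this value, and no biological explanation was tested.

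The number of called loci and lists was set beside the 10 splits of the 6 hearts into 3 and 3. The real split gave 15 loci and the highest other split 0, so 1 of 10 splits reached that number. For gene lists the real split gave 4 and the highest other 5, with 5 of 10 splits giving at least 4. The mean of the fatty acid oxidation list was 0.520 in size in the real split and at most 0.285 in the others. All edKO hearts lay below all WT hearts in this mean, so the real split had to give the largest size, and the order adds no test. These 10 splits are too few for a share under 0.05.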
